A study of Zea mays with 6 samples.

How the data were processed

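Messenger RNA from maize root tips was sequenced in 6 libraries, 3 from plants under negative pressure irrigation (NPI) and 3 from plants in a comparison group called DI. The labels give DI as deficit irrigation in one field and as drip irrigation in another, so the abbreviation is kept here. Per the labels' protocols, total RNA was enriched for poly(A) RNA, fragmented and sequenced as read pairs on an Illumina instrument. The labels do not say whether the libraries came from separate plants or pots, so p-values measure only the spread between these libraries, which may be technical.

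Per the submitters' processing notes, the tools were FastQC 0.10.1, HISAT2 2.0, StringTie 1.3.4 and edgeR, the last with no version. The genome build is not given in the sources used here, and coordinates are those of the deposited table, whose gene identifiers start with Zm00001d. The authors deposited one table of 45953 genes with estimated counts and FPKM per library, beside gene names, product descriptions and annotation terms. The estimated counts in the deposited table are whole numbers, so no further rounding was needed. FPKM in the deposited table is the authors' estimate scaled for transcript length and library size, and it was used for the filter, for the levels printed and for the agreement of libraries. The reference table given beside the data shares no identifiers with the deposited table and was not used. Strand handling is not given in the sources used here, so overlapping genes and near-identical copies may share counts.

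The test had been planned as limma on log2(FPKM + 1). Because the table holds estimated counts, edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) took its place, as the plan allowed. It used TMM factors and the contrast NPI minus DI, was two-sided, and had Benjamini-Hochberg adjustment over the 21902 genes with a mean FPKM of at least 1. The threshold was an adjusted p of 0.05. Log2 differences come from the edgeR fit, and the standard error is the size of the log2 difference divided by the root of the F statistic. Per-library differences are log2 CPM with a prior count of 1, minus the DI mean. Correlations and principal components used log2(FPKM + 1). With 3 libraries against 3, an exact two-sided permutation test of a single value cannot go below p = 0.1.

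Before the data were examined, 34 gene lists were fixed by regular expressions on gene names and descriptions. The patterns missed family members whose names the table spells out, among them 14 aquaporin and 11 SWEET genes, and the other lists were not checked for such gaps. They were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, for lists with at least 5 tested genes. Camera with an estimated correlation and fry stood beside it. The estimated option also tests on far fewer degrees of freedom, so a call lost there need not reflect correlated genes. GO and KEGG terms from the table with 10 to 500 tested genes were tested in the same way. The rule for named genes was also fixed then. It took described genes past the threshold whose groups did not overlap. Because fewer than 5 genes passed, it took in their place the 5 higher and 5 lower described genes with the smallest p. It added the 2 higher and 2 lower members of each list with the smallest p, reported in part, and 7 genes of root biology. Any other gene named was chosen after its values were seen. Of those 7 genes, benzoxazinless1, with a mean FPKM of 0.537, was not tested.

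Total counts ran from 57792439 to 71957443 per library, so counting error is small for most tested genes beside the spread between libraries. On simulated data of 21902 genes with the dispersions fitted to NPI against DI, edgeR recovered 26% of 100 genes changed 4-fold and 84% of 100 changed 16-fold, and called 9 unchanged genes. DESeq2 1.42.0 recovered 72% and 93% and called 77 unchanged genes. In 5 simulated draws with no change, where each group kept its own dispersion, edgeR called at most 2 genes and DESeq2 35 to 51. The alternatives covered the filter, pseudocount, scaling, robust moderation, library weights, a replicate block and each library left out. The limma test first planned was run as well. Those chosen after seeing the data were DESeq2, other scaling factors in edgeR, its newer quasi-likelihood estimate, limma-voom with and without weights per group, limma without the filter, adjusted p of 0.1 and 0.2, counts thinned to the smallest library, removal of a trend with transcript length, and other scales for the correlations. Transcript length was taken as the ratio of deposited count to FPKM, relative to the median gene. Figures were drawn with matplotlib 3.10.9.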

Results

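The transcriptome of maize root tips was compared between plants under NPI, in which soil takes up water from a supply held below atmospheric pressure, and plants under DI. The title of the series frames the question as how NPI inhibits root growth while water use efficiency improves. There were 3 libraries per group. Total estimated counts were 59900871, 65917999 and 64522990 in NPI replicates 1 to 3 and 57792439, 63110564 and 71957443 in DI replicates 1 to 3.

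The DI libraries resembled one another more closely than the NPI libraries did. Pearson correlations of log2(FPKM + 1) across the 21902 tested genes, which are not independent replicates, averaged 0.947 ± 0.011 (SD, 3 pairs) within DI and 0.851 ± 0.045 (SD, 3 pairs) within NPI. Pairs of an NPI and a DI library averaged 0.842 ± 0.036 (SD, 9 pairs). NPI-2 correlated better with DI-1, DI-2 and DI-3 (0.854, 0.882 and 0.866) than with NPI-1 (0.838) or NPI-3 (0.814), which correlated with each other at 0.901. The first component, with 48.5% of the variance, put NPI-1 at -88.6 and NPI-3 at -75.7. NPI-2 lay at 14 on it, nearer to the DI libraries at 26.5 to 70.5. On the second component, with 25.4%, NPI-2 lay at 87.8, above the other 5 libraries.

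**Figure D1:**
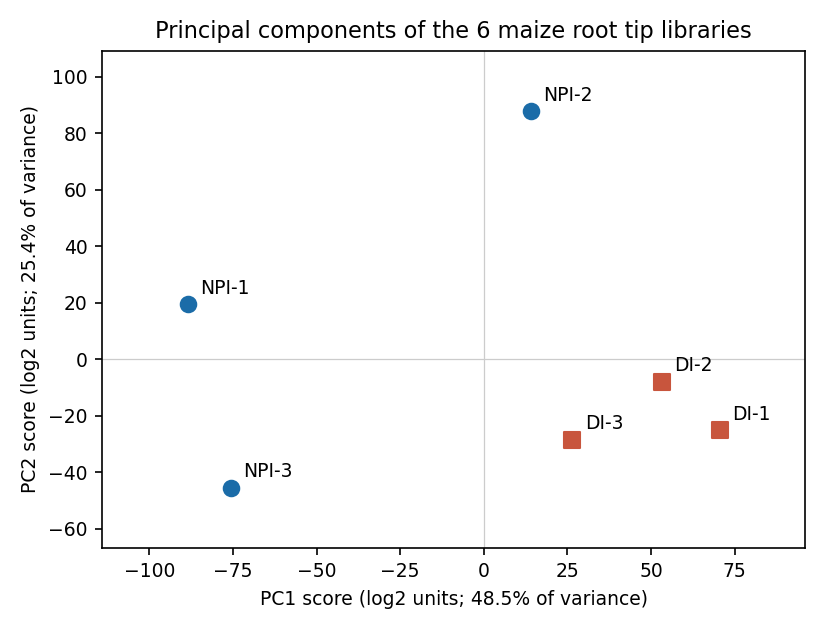
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over the tested genes, in log2 units, with NPI as circles and DI as squares. NPI-1 and NPI-3 lie at -88.6 and -75.7 on the first component, and NPI-2 at 14, close to the DI libraries.

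Under NPI, 2 genes rose and 1 fell. Zm00001d008054, a long intergenic non-coding RNA on chromosome 8 (92434507 to 92434989), rose from 0.13 ± 0.02 FPKM (SD, n = 3) in DI to 276 ± 128 FPKM (SD, n = 3) in NPI. Zm00001d020544 encodes an S-adenosylmethionine decarboxylase proenzyme, the enzyme that provides the aminopropyl donor for spermidine and spermine. It rose from 3.92 ± 1.11 to 55.5 ± 7.23 FPKM (SD, n = 3 each). Zm00001d038703 encodes the O-methyltransferase ZRP4, a type of enzyme described from maize roots, and fell from 61.7 ± 17.3 FPKM in DI to 0.87 ± 0.173 FPKM in NPI (SD, n = 3 each).

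The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave Zm00001d008054 a log2 difference of 10.94 (SE 0.621, adjusted p = 0.00768), higher in 3 of 3 NPI libraries. The non-coding gene had 5 counts in each DI library and 13493, 5489 and 9230 in the NPI libraries, and it was named after its values were seen, since it has no description. For Zm00001d020544, on chromosome 7 (121750712 to 121753167), the log2 difference was 3.88 (SE 0.303, adjusted p = 0.0237, edgeR). For Zm00001d038703, on chromosome 6 (162999184 to 163000694), it was -6.05 (SE 0.394, adjusted p = 0.0101, edgeR). At an unadjusted p under 0.05, 2692 genes were higher and 1866 lower. The groups did not overlap in 26.7% of tested genes, with 2851 higher and 3006 lower. By chance 10% would be expected, but genes move together within a library, so a single split can lie far from that. In other splits of the 6 libraries into 3 and 3, edgeR gave 211 to 3144 genes with unadjusted p under 0.05, beside 4558 in the real split. DESeq2 called 1499 genes higher and 992 lower, and limma on log2(FPKM + 1) called 99 and 39. The edgeR counts turned on single libraries: without NPI-2 there were 1457 higher and 1136 lower, without NPI-1 1 and 0, without NPI-3 1 and 2, and without any 1 of the DI libraries 0 and 0.

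The described genes next in order of p within each direction did not pass in edgeR. A second S-adenosylmethionine decarboxylase gene, Zm00001d020543, lies close by on chromosome 7 (121726371 to 121727549), and counts of such similar genes may be shared. It had 23.9 ± 6.11 FPKM in NPI and 2.43 ± 0.68 in DI (SD, n = 3 each; edgeR adjusted p = 0.058). Higher values in NPI were also found for Zm00001d048507, a major facilitator family transporter, for the lipid binding protein gene Zm00001d042862 and for Zm00001d009927, a 2OG-Fe(II) oxygenase. Their log2 differences were 2.64, 4.34 and 2.33 (edgeR adjusted p = 0.058 for each). Lower values in NPI were found for Zm00001d020134, named ABC transporter G family member 40, whose Arabidopsis namesake imports abscisic acid. It had 2.25 ± 0.682 FPKM in NPI and 32.3 ± 2.18 in DI (SD, n = 3 each; edgeR adjusted p = 0.058). Zm00001d051671, a WD repeat protein gene, Zm00001d027633, named protein PIR after a part of the complex that regulates actin branching, and the RING zinc finger gene Zm00001d039015 had log2 differences of -1.98, -3.08 and -2.33 (edgeR adjusted p = 0.0613 for each). Without NPI-2, all of these passed, each with adjusted p = 0.022.

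**Figure D2:**
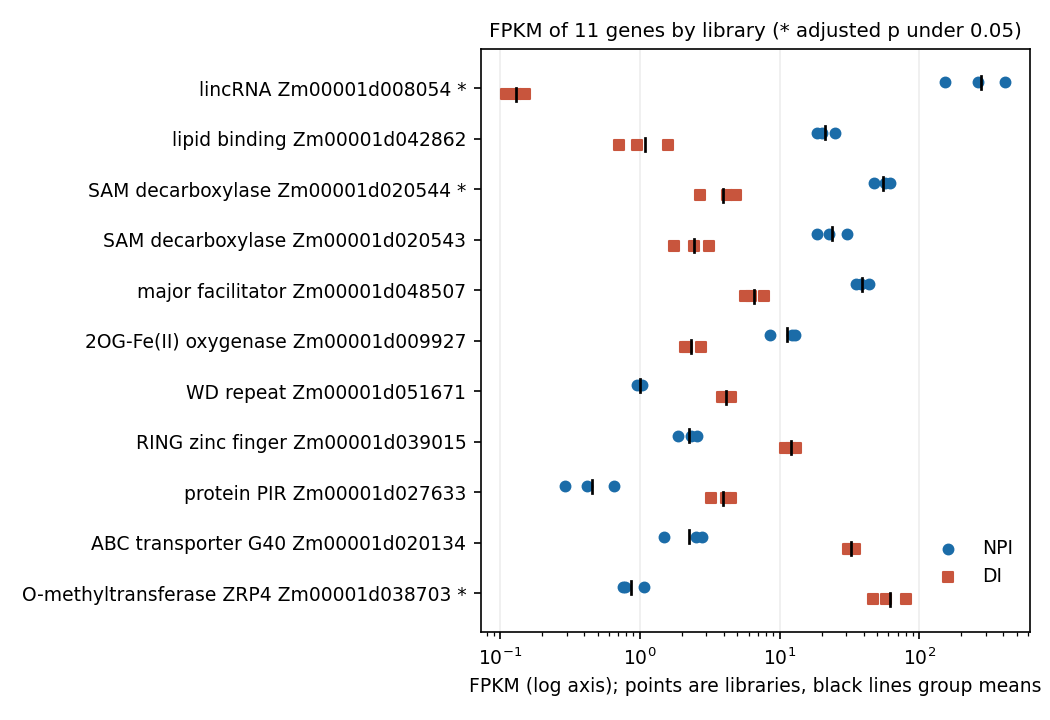
FPKM on a log axis of the 3 called genes, marked with an asterisk, and of 8 further described genes. The 8 have the next smallest p within the higher or within the lower genes. NPI libraries are circles, DI libraries squares and group means black lines. The 3 NPI values of Zm00001d008054 lie near a mean of 276 FPKM and the DI values near 0.13 FPKM.

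Water channels stood out among the gene lists. All 15 tested genes of the aquaporin list, which encode membrane channels that let water into cells, had higher values in NPI, with a median log2 difference of 1.98. The list's pattern missed 14 tested genes of the family whose names are spelled out as intrinsic proteins. A count made after the results were seen gave 11 of those 14 higher, with a median of 1.19, and 26 of 29 in the whole family, with a median of 1.38. The medians of the list were 1.79 in NPI-1, 0.62 in NPI-2 and 2.75 in NPI-3. The list was called higher by camera with the preset correlation (adjusted p = 2.36e-06), and had adjusted p = 0.873 with the estimated correlation, which was 0.682. No aquaporin passed over all genes, and 8 passed when adjusted over the list alone. The gene of aquaporin PIP2-4, Zm00001d017288 on chromosome 5 (191817119 to 191819914), had 45.4 ± 20 FPKM in NPI and 6.81 ± 3.29 in DI (SD, n = 3 each; edgeR adjusted p = 0.0773). That of PIP2-5, Zm00001d003006, had 58.4 ± 49.2 and 6.24 ± 1.83 FPKM (SD, n = 3 each; edgeR adjusted p = 0.0904).

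The lists of xylem and secondary wall genes and of root cap and mucilage genes were also called higher. Of 44 xylem and wall genes, 39 had positive differences, with a median of 0.55 (camera adjusted p = 0.0101, and adjusted p = 0.923 with an estimated correlation). NPI-2 stood apart, with a list median of -0.37 beside 0.78 in NPI-1 and 0.96 in NPI-3. IRX9, a xylosyltransferase of xylan synthesis encoded by Zm00001d010976, had 23.8 ± 5.98 FPKM in NPI and 8.94 ± 0.864 in DI (SD, n = 3 each; edgeR adjusted p = 0.0874). Of 59 root cap and mucilage genes, 48 were positive, with a median of 0.78 (camera adjusted p = 0.0422, and adjusted p = 0.923 with an estimated correlation). NPI-2 stood apart here too, with a list median of -0.07 beside 0.41 and 1.07. The list took in extensin and arabinogalactan genes, structural wall proteins that are not specific to the cap. Among them, the extensin-like gene Zm00001d048799 had a log2 difference of 2.45 (edgeR adjusted p = 0.0874). A gene described as root cap-specific, Zm00001d045420, lay the other way, with 8.78 ± 14 FPKM in NPI and 65.85 ± 37.5 in DI (SD, n = 3 each; edgeR log2 difference -2.99, adjusted p = 0.261, and -6.32 with adjusted p = 0.022 without NPI-2). The list is therefore no measure of the cap itself. Without NPI-3 the xylem call ended at adjusted p = 0.218 and the root cap call at 0.743, and the latter also ended without DI-1 at 0.0828 and without DI-2 at 0.0501 (camera).

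Among transcription factors, the bHLH and MYB lists were called higher. Of 69 bHLH genes, 53 were positive, with a median of 0.63 (camera adjusted p = 0.000737, and adjusted p = 0.693 with an estimated correlation), and adjusted over the list alone 9 passed as higher and 1 as lower. bHLH-transcription factor 127 (Zm00001d014814) had 56.8 ± 23.4 FPKM in NPI and 11 ± 2.91 in DI, and bHLH-transcription factor 35 (Zm00001d027546) had 2.63 ± 0.196 and 11.5 ± 2.6 (SD, n = 3 each; edgeR adjusted p = 0.0619 for both). Of 123 MYB genes, 84 were positive, with a median of 0.23 (camera adjusted p = 0.0397, and adjusted p = 0.923 with an estimated correlation), and 7 higher and 1 lower passed when adjusted over the list alone. The library medians were 0.39, 0.12 and 0.47, and the median without NPI-2 was 0.42. MYB-transcription factor 110 (Zm00001d007191) had 18.8 ± 5.32 FPKM in NPI and 1.94 ± 1.11 in DI (SD, n = 3 each; edgeR adjusted p = 0.0715). The MYB call ended without NPI-1 and without NPI-3, at adjusted p = 0.0953 and 0.16 (camera).

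Genes of phosphate status, chromatin and sugar metabolism lay on the lower side. Of 33 phosphate genes, 23 were negative, with a median of -0.68 (camera adjusted p = 0.000737, and adjusted p = 0.873 with an estimated correlation), and 3 passed as lower when adjusted over the list alone. The gene of SPX domain-containing protein 3, a family that senses phosphate status, had 13.2 ± 8.02 FPKM in NPI and 212.7 ± 114 in DI (Zm00001d044541; SD, n = 3 each; edgeR adjusted p = 0.0716). That of SPX domain-containing protein 1, Zm00001d046500, had 13.2 ± 3.75 and 44.4 ± 18.5 FPKM (SD, n = 3 each; edgeR adjusted p = 0.0969).

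Of 73 core histone genes, 52 were negative, with a median of -0.35 (camera adjusted p = 0.00261, and adjusted p = 0.923 with an estimated correlation). Adjusted over the list alone, 6 were lower and 3 higher. Histone H1-3 (Zm00001d002601), a linker histone that the list's pattern took in, had 160.2 ± 23.7 FPKM in NPI and 616 ± 140 in DI (SD, n = 3 each; edgeR adjusted p = 0.0716). An H2B gene (Zm00001d011236) had 101.5 ± 13.2 and 281 ± 18 FPKM (SD, n = 3 each; edgeR adjusted p = 0.0773). The list median was 0.12 in NPI-3, beside -0.56 in NPI-1 and -0.78 in NPI-2, and without NPI-2 the call ended at adjusted p = 0.212 (camera).

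Enzymes of osmolytes and of sucrose and starch were called lower. Of 35 osmolyte genes, 20 were negative, with a median of -0.36, and of 69 sucrose and starch genes 45 were negative, with a median of -0.28 (camera adjusted p = 0.0162 for both). With an estimated correlation they had adjusted p = 0.873 and adjusted p = 0.636. Adjusted over the list alone, 4 osmolyte genes passed as lower, and 3 sucrose and starch genes as lower and 1 as higher. Zm00001d031300 belongs to both lists, so these calls are not fully separate. The sucrose and starch pattern missed 11 tested SWEET genes, of which 10 were higher in NPI, and the list was not tested again with them. The trehalose-6-phosphate synthase7 gene (Zm00001d043469) had 2.64 ± 0.721 FPKM in NPI and 12.1 ± 1.92 in DI (SD, n = 3 each; edgeR adjusted p = 0.0619). Without NPI-2 the calls ended at adjusted p = 0.235 and 0.0584, and the osmolyte call also without DI-3 at 0.071 (camera).

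**Figure D3:**
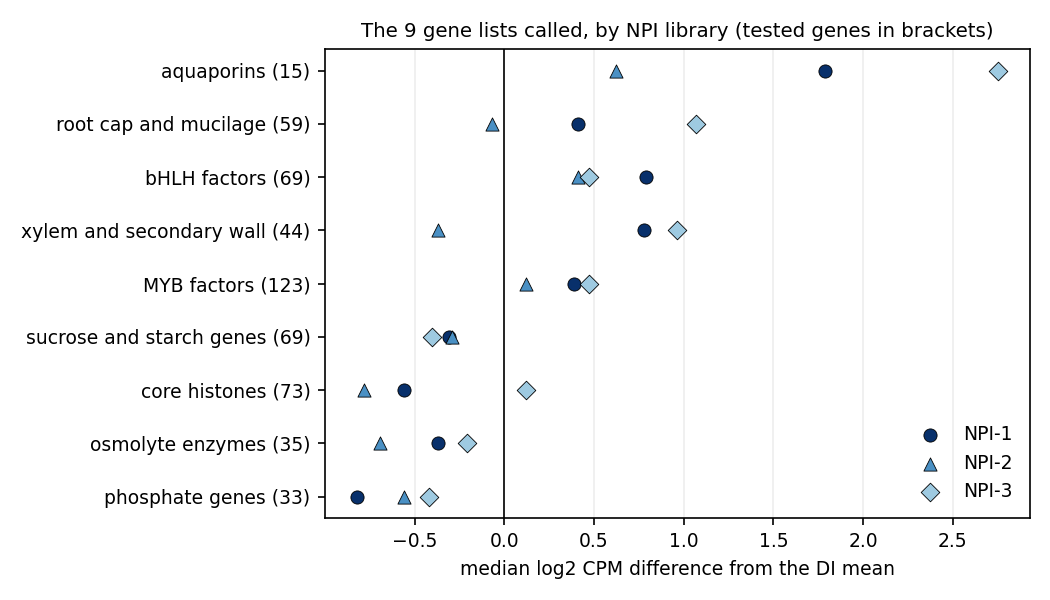
Median difference from the DI mean in log2 CPM for the 9 called lists, with 1 symbol per NPI library and the number of tested genes in brackets. Aquaporins lie at 1.79, 0.62 and 2.75 in NPI-1, NPI-2 and NPI-3, and xylem and secondary wall genes at 0.78, -0.37 and 0.96.

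In all, 9 of the 34 lists were called, 5 higher and 4 lower, and none had a member past the threshold over all genes in edgeR. Adjusted over the list alone, 16 of the 34 lists had a member that passed. Lists not called were among them, such as WRKY factors with 4 higher and 7 lower, so such members do not set the called lists apart. None of the 9 calls held with an estimated correlation, and fry, which asks whether a list moves one way on balance, called none (smallest adjusted p = 0.0641). The estimated option has little power with 6 libraries. For sucrose and starch genes the estimate was -0.002, below the preset 0.01, yet camera's adjusted p went from 0.0162 to 0.636. For that list, loss of the call therefore does not show that correlated genes had made it. Every other called list had an estimate above the preset. The highest were 0.682 in aquaporins, 0.382 in core histones and 0.352 in xylem genes, and the lowest 0.03 in bHLH factors. Their adjusted p with the preset may therefore be too small. Calls with the preset correlation were not particular to the real split: other splits of the same 6 libraries called up to 16 lists. Those splits mix the groups unevenly, so each may keep part of an irrigation difference. The other 25 lists had camera adjusted p from 0.0743 to 0.981. Among them were expansins, auxin genes, ethylene genes, heat shock proteins, class III peroxidases and the cell cycle genes. Without NPI-2, ethylene genes were called higher and cell cycle and ribosomal protein genes lower (camera adjusted p = 0.0112, 0.0352 and 3.17e-06). The median, mean and test of a list differed in sign in 8 lists, which were the gibberellin, cytokinin, hypoxia, defence, benzoxazinoid, ribosomal protein, photosynthesis and NAC lists. The expansin list was not called, with 21 of 36 genes negative and a median of -0.16, while adjusted over the list alone 6 were higher and 1 lower. Its member of smallest p, alpha expansin2 (Zm00001d018031), of a family that loosens walls in growing cells, had 40.5 ± 9.6 FPKM in NPI and 3.74 ± 1.04 in DI (SD, n = 3 each; edgeR adjusted p = 0.0608). The auxin-responsive SAUR12 gene Zm00001d018200 had 44.8 ± 18.1 and 4.85 ± 1.03 FPKM (SD, n = 3 each; edgeR adjusted p = 0.0613).

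None of the genes of root biology chosen in advance passed in edgeR. Alcohol dehydrogenase1 (Zm00001d033931), a marker of low oxygen, had 1571 ± 674 FPKM in NPI and 1546 ± 40.2 in DI (SD, n = 3 each; edgeR adjusted p = 0.915). Dehydrin1 (Zm00001d037894), induced by abscisic acid and drying, had 186.7 ± 149 and 71.8 ± 32.4 FPKM, and viviparous14 (Zm00001d033222), an enzyme of abscisic acid synthesis, 3.25 ± 1.55 and 1.07 ± 0.852 FPKM (SD, n = 3 each; edgeR adjusted p = 0.395 and 0.244). The root hair genes roothair defective1 (Zm00001d033303) and roothair defective3 (Zm00001d028826) had log2 differences of -0.31 and 0.11 (edgeR adjusted p = 0.486 and 0.937). Rootless concerning crown and seminal roots1 (Zm00001d027679) had 10.1 ± 14 FPKM in NPI and 2.9 ± 1.05 in DI (SD, n = 3 each; edgeR adjusted p = 0.338). Its NPI mean came from NPI-3 at 26.2 FPKM, beside 1.91 and 2.11, and without NPI-3 the log2 difference was -0.53.

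Shorter transcripts had higher values in NPI. Across the 21902 genes, which are not independent replicates, the log2 difference had a Spearman correlation of -0.252 with relative transcript length. The shortest decile had a median difference of 0.48 and the longest -0.24. The direction was the same in each NPI library, with medians in the shortest decile of 0.37, 0.24 and 0.58. With this trend removed, aquaporins, phosphate genes, core histones, xylem genes and bHLH factors stayed called, and the osmolyte, sucrose and starch, root cap and MYB calls ended. Their medians were -0.36, -0.28, 0.78 and 0.23 before and -0.22, -0.14, 0.53 and 0.27 after, so that of MYB did not fall. The median of core histones went from -0.35 to -0.69, and ribosomal proteins became called as lower (camera adjusted p = 0.0236, beside 0.432 before).

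**Figure D4:**
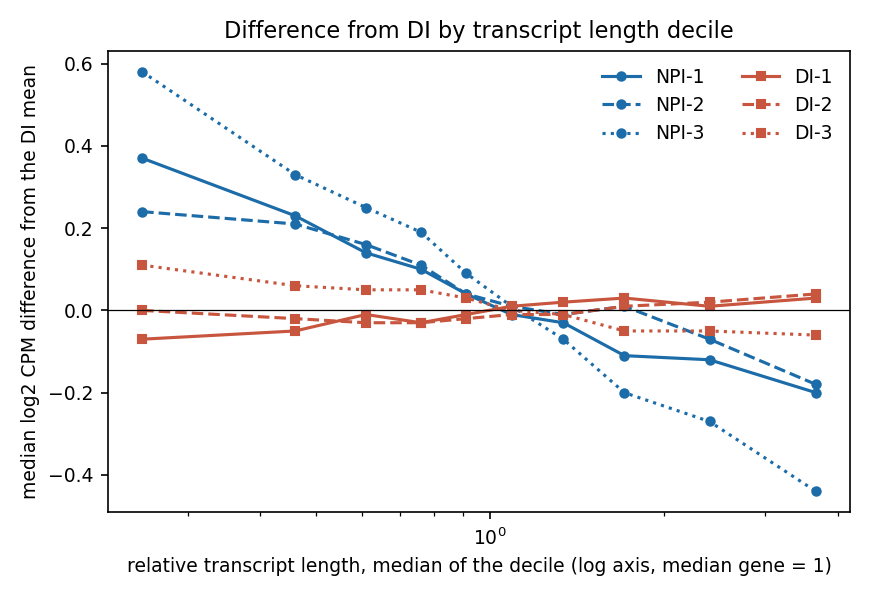
Median difference from the DI mean in log2 CPM by decile of relative transcript length (log axis), 1 line per library. In the shortest decile the NPI libraries lie at 0.37, 0.24 and 0.58 and the DI libraries between -0.07 and 0.11.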

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

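The tests of organelle and small nuclear RNA were chosen after the shares were seen, and those of the lincRNA share were set once the share was known but before their own results. Mitochondrial, plastid, small nucleolar, small nuclear and lincRNA genes each took more of the counts in every NPI library than in any DI library, whereas tRNA and nuclear ribosomal RNA did not (exact p = 0.4 and 0.9). Mitochondrial genes held 0.0821% ± 0.026 of the counts in NPI and 0.0212% ± 0.0042 in DI, mostly ribosomal RNA of the mitochondrion (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). Small nucleolar RNAs held 0.0164% ± 0.0092 and 0.0044% ± 2e-04, and small nuclear RNAs 0.00533% ± 0.0025 and 0.00113% ± 0.00023 (SD, n = 3 each; exact p = 0.1 for both). Plastid genes held 5e-04% and 3e-04%, and lincRNAs 0.363% ± 0.098 and 0.202% ± 0.031 (SD, n = 3 each; exact p = 0.1 for both).

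Genomic DNA in the NPI libraries would add counts to silent genes. Genes with counts that were silent in all libraries of the other group numbered 692 ± 31 in NPI and 827 ± 51 in DI (SD, n = 3 each, a difference of -135, SE 35). NPI thus lacked the excess that DNA would bring. However, DI libraries also held counts in more genes in all, 28993 ± 303 beside 28475 ± 382 in NPI (SD, n = 3 each). Such a difference in breadth could mask a small amount of DNA, so DNA stays open. A general carry-over of RNA without a poly(A) tail would raise nuclear ribosomal RNA too. Its share differed by a ratio of only 1.06 between NPI and DI. That share was 0.0031% in NPI and 0.00293% in DI, beside 0.0769% and 0.0188% for mitochondrial ribosomal RNA. With so little nuclear ribosomal RNA in the counts, the ratio cannot decide on a general carry-over, which stays open. A carry-over limited to some classes, RNA quality and a biological difference between the irrigation groups stay open too and were not tested.

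The 191 tested lincRNA genes lay 0.57 (bootstrap SE 0.105) above protein-coding genes of like length on the log2 scale. In these 6 libraries, that argues against the length trend as the whole cause of the lincRNA share. The SE comes from resampling genes, so it does not measure the spread between libraries. Genes were matched on length and not on level. Nor did the called gene Zm00001d008054 alone make the share: without it the lowest NPI share was 0.281% and the highest DI share 0.236%.

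The second pattern is NPI-2, which correlated better with the DI libraries (0.854, 0.882 and 0.866) than with NPI-1 (0.838) or NPI-3 (0.814); the first test of a mixture with DI RNA was planned before its result and the others came after. A DI sample under a wrong label would match DI libraries as they match one another, at 0.936 or more, whereas the highest correlation of NPI-2 with a DI library was 0.882. DI RNA mixed in at a smaller share stays open, because NPI-2 was over 2-fold outside the other 5 libraries in 3.2% of genes, a margin over NPI-1 at 2.9% and NPI-3 at 3% that is within the spread between libraries. The share of 62.7% that the 808 genes lower without NPI-2 and with at least 5 FPKM in DI would need at the median is argued against as the whole cause if the source resembled the DI libraries, since for each pair of DI libraries 377 or more genes in NPI-2 lay under 31.3% of the lower value, beside at most 64 in the remaining DI library. Depth is argued against by a mean correlation within NPI of 0.827 after thinning to one depth, below the lowest in DI of 0.921, while another share of growing tip and mature root in the tissue stays open, with 4 of 6 marker lists on the side it predicts and the histone and root hair lists not.

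The third pattern is the calls of gene lists beside the length trend, and these tests came after the trend was seen. With the trend removed from each library, 5 of 5 lists (aquaporins, phosphate genes, core histones, xylem genes and bHLH factors) stayed called, and the median was 1.87 after and 1.98 before in aquaporins and -0.69 and -0.35 in core histones, while ribosomal proteins became called as lower. Of the 4 lists of osmolyte, sucrose and starch, root cap and MYB genes, 0 stayed called, with medians of -0.36 (bootstrap SE 0.26), -0.28 (0.11), 0.78 (0.19) and 0.23 (0.09) before and -0.22 (0.22), -0.14 (0.09), 0.53 (0.14) and 0.27 (0.1) after. The osmolyte, sucrose and starch and root cap medians became smaller, and in MYB the median did not fall while the mean went from 0.52 to 0.44. These SEs belong to the medians and do not measure the change between them. The trend stays open as a cause for these 4, and the end of the MYB call does not count as evidence for it.

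The 6 libraries allow 10 splits into 3 and 3, so no share under 0.05 can be had, and this test was set before its result. The real split gave 2 genes higher and 1 lower in edgeR, and the highest of the other splits 0. For gene lists it gave 9 and the highest other split 16, with 8 of the 10 splits at 9 or more. For annotation terms it gave 196 and the highest other 368, with 3 splits as large. The split of NPI-1, NPI-3 and DI-1 against the rest gave the 368. The number of lists or terms called was therefore not particular to the real split. Each other split sets 2 libraries of one group and 1 of the other against the reverse, so it may keep part of an irrigation difference. Such splits cannot show how many would be called without that difference.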

How the results depend on the processing

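Settings chosen after seeing the data are named as added. For each setting, the count of genes higher is given before that of genes lower, against 2 and 1 in edgeR. The counts were 13 and 5 with no filter and 11 and 4 with a mean FPKM of at least 5. In limma they were 99 and 30 on log2(FPKM + 0.1), 117 and 59 with FPKM rescaled to one sum, 68 and 21 by median ratio, 133 and 60 after quantile normalization, and 996 and 913 with library weights, where NPI-2 had the lowest weight of 0.247. The limma test on log2(FPKM + 1) that edgeR replaced gave 99 and 39. Added settings gave 1499 and 992 in DESeq2, 11 and 4 with library size only, 17 and 9 with the newer quasi-likelihood estimate, 391 and 232 at an adjusted p of 0.1, 1988 and 1354 at 0.2, 1 and 1 in limma-voom, 15 and 1 in limma-voom with weights per group, 5 and 2 in limma on log2(FPKM + 1) without a filter, and 1303 and 987 with the length trend removed and NPI-2 left out. Leaving out 1 library gave 0 to 1457 genes higher and 0 to 1136 lower, with both highest values without NPI-2. Robust moderation, DESeq2's size factors, removal of the length trend, thinning and a minimum log2 difference of 1 kept 2 and 1. DESeq2 gave no adjusted p for 196 genes. The cause was not tested. The pseudocount, scalings and weights planned for FPKM were run in limma, so these settings change the tool as well. At an unadjusted p under 0.05, more genes were higher in edgeR (2692 and 1866), but more were lower with FPKM rescaled to one sum (1951 and 2458), after quantile normalization (2373 and 2475) and with library weights (3166 and 3850).

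The replicate numbers share no stated origin, and deviations of same-numbered libraries correlated at -0.236, 0.169 and 0.162, which gave no sign that the numbers pair the samples, and NPI-1 correlated best with DI-3. The number of DI-2 is itself in doubt, since its description gives repeat 3. With the replicate block, 1 gene was higher and 0 lower, 9 lists and 166 terms were called, and the root cap list had adjusted p = 0.0546.

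Gene lists called stayed between 6 and 11 in all settings but camera with an estimated correlation and directional fry, which both called 0, and fry for change in either direction, added, which called 19 lists and 919 terms. They ranged from 8 to 11 with 1 library left out. No called list turned its direction. Aquaporins, phosphate genes and bHLH factors were called in 21 of 23 settings each and root cap genes in 11. Those 21 settings all used camera with the preset correlation, so they do not test the preset. The 2 settings without a call were the estimated correlation and directional fry. Terms called were 196, 0 with an estimated correlation, 113 with the length trend removed and 99 to 271 with 1 library left out, the lowest without NPI-3. Agreement within DI moved to 0.934 on log2 CPM and 0.926 on log2(FPKM + 0.1), and between groups to 0.799 on the latter.

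Over 627 pairs of a named gene and a setting, 419 kept the direction and side of the threshold, 176 passed where the main test did not, 14 lost the threshold and 18 turned direction. The 3 called genes lost it with any DI library left out. Zm00001d020544 and Zm00001d038703 also lost it with the replicate block and without NPI-1, and the former without NPI-3. Alcohol dehydrogenase1 was -0.09 in limma with either pseudocount, -0.15 rescaled to one sum, -0.04 by median ratio, -0.28 after quantile normalization, -0.02 with the replicate block and -0.09 without NPI-1 or NPI-3, with a highest value of 0.48 without NPI-2. Roothair defective3 was -0.14 and -0.13 with pseudocounts of 0.1 and 1, then -0.19, -0.07, -0.25 and -0.06 in the same order, -0.36 without NPI-3 and -0.16 without DI-1, with a highest value of 0.54 without DI-3. Roothair defective1 was 0.01 with the length trend removed, and rootless concerning crown and seminal roots1 -0.53 without NPI-3 and 2.48 without NPI-1 or NPI-2.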

Other observations

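Sugar transporters, genes of nutrient reservoir activity and kinesins stood out in the search over annotation terms. The genes named here were chosen after their values were seen. The 11 genes of sugar transmembrane transporter activity all had higher values in NPI. All are SWEET genes, of a family of sugar transporters, and Zm00001d043735 among them is described as bidirectional. Their median log2 difference was 1.98, with 2.15, 1.12 and 1.94 in NPI-1 to NPI-3 (camera adjusted p = 1.74e-05, and adjusted p = 0.979 with an estimated correlation). Sugars will eventually be exported transporter4a (Zm00001d015905), on chromosome 5 (130027454 to 130030346), had 84 ± 34.5 FPKM in NPI and 12.3 ± 4.24 in DI (SD, n = 3 each; edgeR adjusted p = 0.0715). This group lies on the other side from the sucrose and starch list, which was called lower and whose pattern, meant to include SWEET genes, took in 1 of the 12 tested. Of the 11 it missed, 10 were higher in NPI, with a median of 1.52. These are largely the genes of the term above, so the count is no separate result. All 10 genes of the brassinosteroid biosynthesis pathway also had higher values, with a median of 1.42 (camera adjusted p = 0.00551, and adjusted p = 0.979 with an estimated correlation).

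The largest lower group by median was nutrient reservoir activity, 28 genes with a median of -2.68 and library medians of -3.42, -4.04 and -1.43 (camera adjusted p = 2.24e-06, and adjusted p = 0.979 with an estimated correlation). Of these, 7 were higher, among them the one of smallest p, the legumin-like gene Zm00001d011036 with 36.7 ± 14.9 FPKM in NPI and 3.96 ± 1 in DI (SD, n = 3 each; edgeR adjusted p = 0.0619). Many of the 28 are germin-like proteins, secreted proteins of the cell wall space. Of 17 tested genes on chromosome 4 described as germin-like protein subfamily 1 member 8, 16 had lower values in NPI. In 13 of the 17 the groups did not overlap, whereas over all tested genes they did not overlap in 26.7%. The 17 genes were singled out after their values were seen, so this count is not a test. One of them, Zm00001d049433, had 2.14 ± 1.67 FPKM in NPI and 29.4 ± 12.1 in DI (SD, n = 3 each; edgeR adjusted p = 0.0829). Such similar copies may share counts, so they are not independent of one another. Of 62 kinesin complex genes, motors that move along microtubules, 52 were lower, with a median of -0.71 and library medians of -1.24, -0.47 and -0.77 (camera adjusted p = 1.31e-06, and adjusted p = 0.979 with an estimated correlation). These are long genes, and with the length trend removed the median was -0.5. Other lower terms with camera's preset correlation were tRNA aminoacylation for protein translation, where 53 of 59 genes were lower but the median was -0.08 in NPI-2 beside -0.9 and -0.68, and DNA topoisomerase activity with 10 of 10 and library medians of -1.55, -0.54 and -1.32. Both had adjusted p = 0.979 with an estimated correlation. In all 196 of 1293 terms were called, 31 higher and 165 lower, and 0 with an estimated correlation; without NPI-3 the count was 99.

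The last test asked whether NPI-2 shares the direction of the other NPI libraries, and it was chosen after the list medians of NPI-2 had been seen. Of the 2593 genes called without NPI-2, 77.5% lay on the same side of DI in NPI-2. The comparison shares its DI libraries with the choice of genes, and 20 simulated draws with no change gave 60.3% on average and at most 61.1%. Genes in those draws were independent, whereas real genes move together within a library. The draws therefore cannot show how far the share could move in 1 library without an effect of irrigation. The median log2 difference of the higher genes was 0.69 in NPI-2 and 1.95 in NPI-1 and NPI-3, and that of the lower genes -0.49 and -1.62. Such smaller sizes would also follow from DI RNA in NPI-2 at a smaller share, which stays open. The test above was made for a share of 62.7% and does not give the highest share that stays open. Of the 808 lower genes used there, 223 lay above the DI mean in NPI-2, and the spread to be expected was not tested. Because genes were chosen on NPI-1 and NPI-3, their values there are inflated by the choice. DESeq2 on all 6 libraries and edgeR without NPI-2 shared 978 genes higher and 494 lower, but both used the same 5 libraries, so the overlap is not independent evidence.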
